A study of Zea mays with 42 samples.

How the data were processed

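Total RNA from maize seedling roots of the inbred lines Lo5 and T250 was labelled with Cy3 and hybridized to NimbleGen single-colour expression arrays, per the labels, 1 sample per array and 42 arrays in all. The deposited values are probe intensities on a linear scale, quantile normalized by the submitters within each line: the sorted values of all arrays of a line were the same to within 0.342% in Lo5 and 0.437% in T250, with a deposited median of 528 in Lo5 and 537 in T250. The submitters' notes name RMA without its role, and its version and the scanner and image software are not given in the sources used here. The combined value table and the deposited intensity files per array held the same values for 140663 probes.

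Of these probes 139000 belong to 59756 transcript models of 39219 genes, 2 or 3 probes for nearly every model, and 1663 are random-sequence controls. The controls were left out of the gene tests. Gene identifiers are those of the array. Names came from a reference gene table that matched 18691 of the gene models, 519 of them to several genes, and gave a name to 2518; this table served for names only, and positions on the genome were not used here.

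The values were taken to log2, quantile normalized again over all 42 arrays, summarised to transcript models by median polish (10 iterations) and averaged per gene in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3). No second background correction was made, since the deposited values are already processed; the plan made before had named the normexp correction for this case, and it was run as an alternative. A gene counted as above background on an array when a probe of it exceeded the 95th percentile of the random-sequence probes of that array. Where a group on the lower side of a difference had a mean level under that percentile, the fold is given as a lower bound, computed with the percentile of each array in place of lower values. Medians of lists are also given with a member at its bound where a group lay below background on all its arrays.

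All 39219 genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on 14 group means from all 42 arrays, two-sided, with Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were nitrate against chloride at each time and as the mean of 3 times per line, the change of that difference from the first to the last time, the difference between the lines, the chloride controls against 0 h, and the lines at 0 h. Sets of genes were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation. The p-values were adjusted over the 21 lists with at least 3 members of the 26 lists written beforehand. The plan matched patterns to gene descriptions, symbols and identifiers. The name table has no descriptions, so the patterns were matched to gene names instead, a departure from the plan that leaves out unnamed members. The lists for ammonium transport and ribosomal proteins had 0 members in this way, which does not show that the array lacks such genes. Another 24 families were formed from gene names afterwards. The design, the tests, the lists and the rule for named genes were fixed before the data were examined. That rule took, among genes that passed the test and had a name, the 10 largest rises and falls of each mean nitrate effect with the same sign at all 3 times, the 5 largest of every other comparison, up to 4 members of each list by p, and all nitrate reduction and high-affinity transport genes. Of the genes the rule took, the text prints those for which no group on the higher side of the difference had a mean level under the 95th percentile where a group on the lower side had, and whose call held on leaving out any 1 array. These restrictions and the rule for lower bounds were made after the values were seen.

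The test was tried on simulated data, drawn from the fitted spread of each gene with known changes added. For a single time 12% of genes changed by 0.5 on the log2 scale were called, 70% of those changed by 1 and 94% of those changed by 2, and 8.05% of the calls were unchanged genes. For a mean of 3 times these shares were 74%, 96% and 100%, with 2.12% of the calls unchanged genes. The noise was drawn independently for each gene and array, so shifts shared by many genes of an array were left out. The shares of unchanged genes therefore do not measure the false calls in the real arrays.

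The alternatives were the normexp correction with an offset of 50 or 0, the normalization as deposited, a filter on dim genes, the brightest transcript model, the median over probes, each line or only the compared arrays in the fit, array weights, the replicate number or the slide as a block, the random-probe level as a covariate, only the times within a slide, and leaving out each array in turn. The slide of an array and its place on it were read from the scan names in the files. A scan number that occurs in both lines at the same 12 places was read as a separate slide in each line; the probe deviations of these 12 pairs had a median correlation of 0.0878, against 0.00755 for other pairs of both lines. The plots were drawn with matplotlib 3.10.9.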

Results

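Gene expression was measured in seedling roots of 2 maize inbred lines, Lo5 and T250, on 42 single-colour arrays with 1 root sample on each. Roots were collected at 0 h and after growth in a nutrient solution that held 200 µM potassium nitrate or, as the control, potassium chloride. The times were 1, 2 and 4 h in Lo5 and 5, 11 and 12 h in T250. Each of the 14 groups held 3 arrays, which the labels describe as independent experiments. On every array 139000 probes covered 39219 gene models, and 1663 probes of random sequence, which match no transcript, gave the background. Between 47.2% and 76.6% of the gene models had a level above the background percentile of the random-sequence probes of an array. These shares use the summarised level of a gene, not the rule above that counts a gene by any of its probes. The number of arrays, 3 per group, limits the precision of every value. Differences below are log2 differences ± the standard error of the limma fit, and levels are log2 intensities ± SD with n = 3.

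The median level of the random-sequence probes moved with some of the groups in Lo5. As log2 differences of nitrate from chloride it moved by -0.26 at 1 h, 0.39 at 2 h and -0.35 at 4 h. Fitted alone, 25.7% of these probes passed the test between nitrate and chloride at 2 h, against 0 at 1 h and 0.481% at 4 h (limma). In T250 the share was 0 at 5 h and at 11 h and 1.20% at 12 h. The Lo5 arrays with nitrate at 2 h lay on another slide than those with chloride at 2 h, whereas at 1 h and at 4 h both groups shared a slide. T250 at 5 h and at 12 h were also each on a single slide, and T250 at 11 h had 1 nitrate array, replicate 1, on another slide than the rest. The scan setting differed between the Lo5 slides too. It was 560 for 0 h, both 1 h groups and 2 h chloride, and 580 for 2 h nitrate and both 4 h groups. Within these slides the groups lay at different places. In Lo5 chloride lay at places 4 to 6 and nitrate at 7 to 9 at 1 h, and at 7 to 9 and 10 to 12 at 4 h. At 2 h in Lo5 nitrate lay at 4 to 6 on its slide and chloride at 10 to 12 on the other. In T250 nitrate lay at 4 to 6 and chloride at 7 to 9 at 5 h, and at 7 to 9 and 10 to 12 at 12 h. At 11 h the groups shared no place either. Treatment and place on the slide therefore cannot be told apart at these times. At places 4 to 6 the random-probe medians were 6.12 to 6.43 on 1 Lo5 slide and 6.23 to 6.31 on the other. At 7 to 9 they were 5.92 to 6.02 and 6.11 to 6.32, and at 10 to 12 5.85 to 5.90 and 5.69 to 5.99. On both slides places 4 to 6 had higher levels than places 10 to 12.

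**Figure D1:**
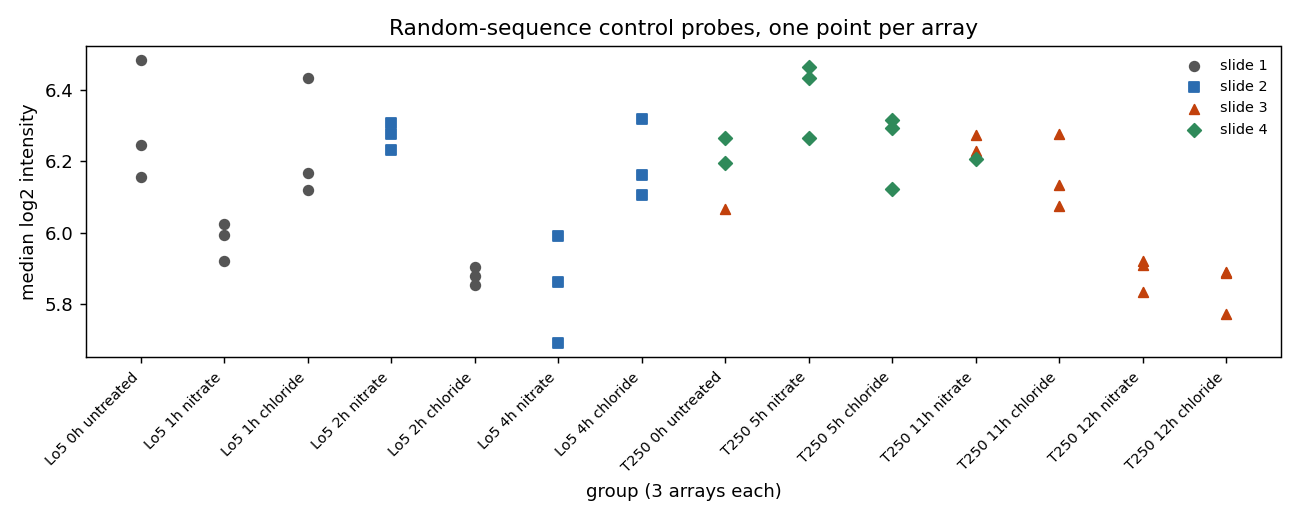
Median log2 intensity of the random-sequence control probes (vertical axis) in each of the 14 groups (horizontal axis), with 1 point per array and a marker for each of the 4 slides. In Lo5 the nitrate group lies below the chloride group at 1 h and at 4 h, with mean differences of -0.26 and -0.35, and above it at 2 h, by 0.39.

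The first question was which genes answer nitrate in T250 roots, as the mean over 5, 11 and 12 h of nitrate against the chloride control. The genes that reduce nitrate and nitrite rose together. Nitrite reductase, NIR (GRMZM2G079381), was 10.5-fold higher with nitrate (3.40 ± 0.15, adjusted p = 6.2e-17), and nitrate reductase, NAR (GRMZM5G878558), 5.63-fold higher (2.49 ± 0.15, adjusted p = 2.6e-14). All 6 measured members of the list for nitrate and nitrite reduction rose, with a median of 2.02 (camera, adjusted p = 2.6e-16, and 0.0034 with an estimated correlation); the count was also 6 when adjusted over the list alone. Of the other members GRMZM2G102959 rose by 2.76 ± 0.16 and NNR1 (GRMZM2G568636) by 1.55 ± 0.16, NNR1 in 8 of 9 nitrate arrays. The siroheme methyltransferase sum1 (GRMZM2G105604), which makes the cofactor of nitrite reductase, was at least 5.91-fold higher. The gene with the largest fitted rise that has a name was NIP1-1 (GRMZM2G041980), of the aquaporin family of intrinsic proteins, at least 7.58-fold higher (adjusted p = 1.6e-16). The differences at the other genes named here had the same sign in 9 of 9 nitrate arrays when each was set against the mean of its chloride group.

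Genes of ammonium assimilation and reductant supply and haemoglobin genes changed in T250 as well. Of the 14 members of the ammonium assimilation list 8 rose and 3 fell (adjusted p = 6.7e-05, and 0.011 with an estimated correlation), and adjusted over the list alone 10 rose and 4 fell. Glutamine synthetase gln3 (GRMZM2G046601) was 8.20-fold higher (3.04 ± 0.16) and gln1 (GRMZM2G098290) 4.00-fold higher (2.00 ± 0.12), whereas gln1-3 (GRMZM5G872068) fell by 0.77 ± 0.07. GRMZM2G078472, also of this list, rose by 1.62 ± 0.09. Of the 9 genes listed for reductant supply 3 rose, also when adjusted over the list alone (adjusted p = 0.00045, and 0.014 with an estimated correlation): ferredoxin FDX6 (GRMZM2G106190, at least 3.45-fold), ferredoxin-NADP reductase fnr1 (GRMZM2G058760, 1.51 ± 0.12) and 6-phosphogluconate dehydrogenase pgd3 (GRMZM2G440208, 0.94 ± 0.07). Of the 2 listed haemoglobin genes 1 rose, also when adjusted over the list alone: Hb2 (GRMZM2G168898) was at least 3.30-fold higher, and HB2 (GRMZM2G161435) lay below background on every T250 array. Outside the list the haemoglobin gene GLB1 (GRMZM2G067402), also under the symbol Hbm, rose by 2.49 ± 0.13.

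Among the 15 nitrate transport genes 5 rose and 1 fell in T250, and adjusted over the list alone 7 rose and 1 fell (adjusted p = 0.0013, and adjusted p = 0.11 with an estimated correlation). The high-affinity nitrate transporter nrt2.2 (GRMZM2G010251) was 5.00-fold higher (2.32 ± 0.21), and its partner protein gene NAR2.1 (GRMZM2G179294) 2.14-fold higher (adjusted p = 7.1e-06). GRMZM2G010280, which the name table lists under both nrt2.1 and nrt2.2, rose by 1.33 ± 0.18. The difference at nrt2.2 arose between 5 h and 11 h, when the chloride controls dropped: at 11 h the level was 14.95 ± 0.10 with nitrate and 11.44 ± 0.50 with chloride, against 14.24 ± 0.12 at 0 h. Of 8 aquaporins 4 rose, also when adjusted over the list alone (adjusted p = 0.0028, and adjusted p = 0.11 with an estimated correlation), PIP2-4 (GRMZM2G154628) among them with 0.51 ± 0.09.

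**Figure D2:**
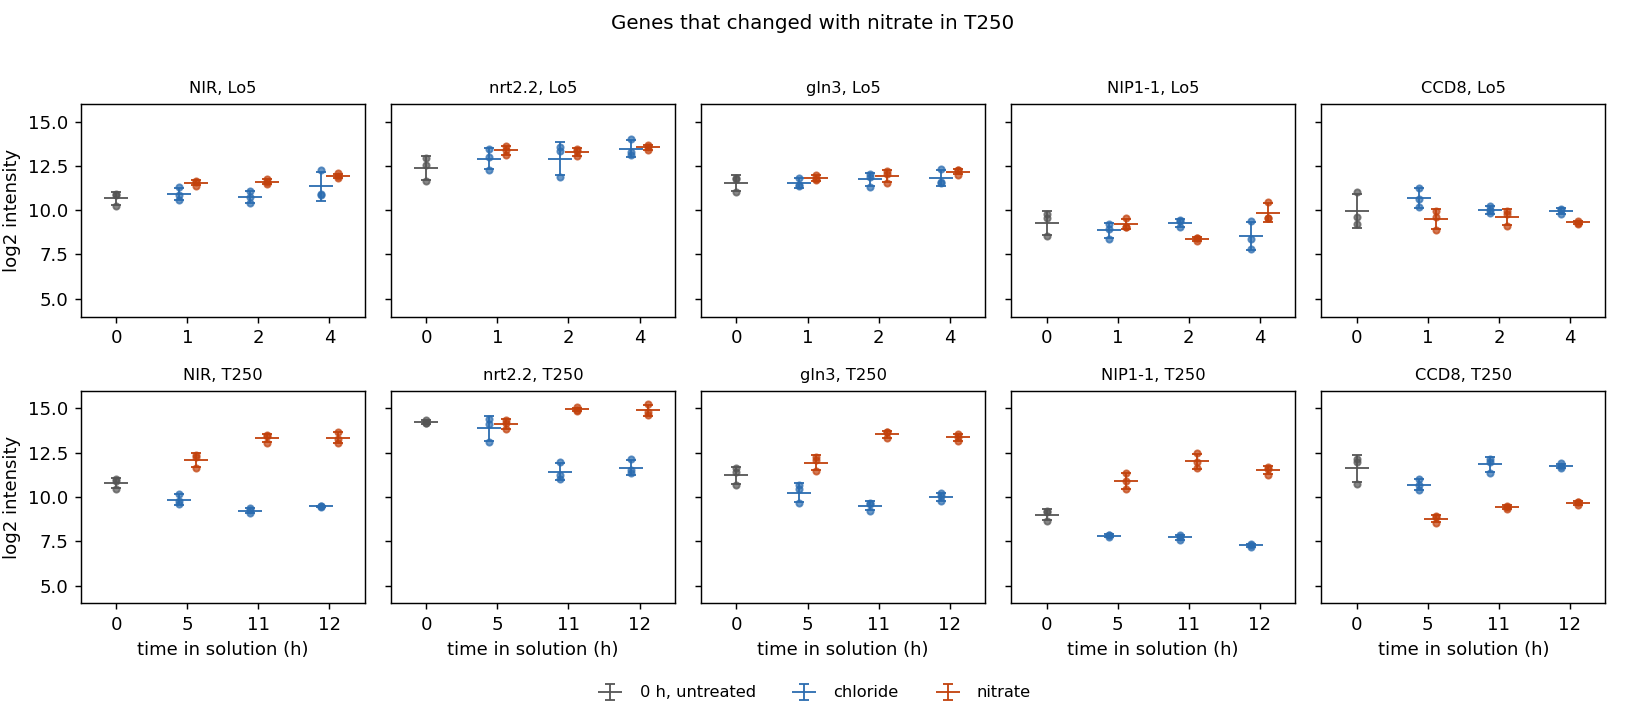
Log2 intensity (vertical axis) against hours in solution (horizontal axis) for NIR, nrt2.2, gln3, NIP1-1 and CCD8 in Lo5 (upper row) and T250 (lower row); points are single arrays, bars the mean ± SD of 3 arrays. In T250 at 12 h NIR lies at 13.34 with nitrate and 9.47 with chloride, and CCD8 at 9.67 and 11.78.

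Hormone and phosphate genes also moved in T250. Of the 13 genes of the cytokinin list 9 rose, 10 when adjusted over the list alone (adjusted p = 6.3e-06, and 0.021 with an estimated correlation): the cytokinin oxidase gene CKX6 (GRMZM2G404443) was 2.35-fold higher (1.23 ± 0.14), and the response regulators RR4 (GRMZM2G319187) and RR6 (GRMZM2G129954) rose by 0.85 ± 0.08 and 0.66 ± 0.11. Both genes listed for strigolactone synthesis fell, also when adjusted over the list alone: CCD8 (GRMZM2G446858, at least 4.05-fold lower) and CCD7 (GRMZM2G158657, -0.93 ± 0.16). The isoprenoid gene dxs2 (GRMZM2G493395) fell by 1.88 ± 0.20, and psy2 (GRMZM2G149317), phytoene synthase, was at least 1.75-fold lower. Of 4 sulfate and phosphate transporters 3 fell, also when adjusted over the list alone (adjusted p = 0.0028, and adjusted p = 0.080 with an estimated correlation), among them pht2 (GRMZM2G154090, -1.13 ± 0.15) and pht1 (GRMZM2G326707, -1.02 ± 0.13). Of 18 ethylene and jasmonate synthesis genes 1 rose and 5 fell, over all genes and when adjusted over the list alone (adjusted p = 0.0038, and adjusted p = 0.19 with an estimated correlation), among the falls opr5 (GRMZM2G087192, -0.77 ± 0.14). The gene with the largest fitted fall that has a name was YS3 (GRMZM2G063306), which exports iron-binding phytosiderophores, at least 3.39-fold lower. The transcription factor gene NAC12 (GRMZM2G018436, -1.46 ± 0.14) fell, and GLK52 (GRMZM2G124495) rose by 1.93 ± 0.17.

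In all, 2691 genes rose and 3918 fell in the mean of T250 (limma, adjusted p under 0.05), of which 181 and 306 differed by at least 1 on the log2 scale. With the slide as a block in the fit 2139 rose and 3445 fell.

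At single times in T250 the same direction was seen from 5 h on. At 5 h NIP1-1 (GRMZM2G041980) was at least 4.04-fold higher, NIR (GRMZM2G079381) 4.64-fold (2.21 ± 0.27), sum1 (GRMZM2G105604) at least 2.35-fold and gln3 (GRMZM2G046601) 3.24-fold (1.70 ± 0.27). Also at 5 h gln1 (GRMZM2G098290) rose by 1.09 ± 0.20 and FDX6 (GRMZM2G106190) by 0.98 ± 0.17, and CCD8 (GRMZM2G446858, at least 2.92-fold), dxs2 (GRMZM2G493395, -1.84 ± 0.35) and the terpene synthase TPS8 (GRMZM2G038153, -1.65 ± 0.25) fell. Of the 6 reduction genes 3 rose, 4 when adjusted over the list alone (median 0.99, adjusted p = 1.3e-08, and 0.040 with an estimated correlation). Fitted with only the 6 arrays compared sum1, gln3, gln1, FDX6 and TPS8 did not pass (adjusted p from 0.068 to 0.15), and with the brightest transcript model gln1 had 0.50 and did not pass. In total 94 genes rose and 144 fell at 5 h. In the fit of the 6 arrays the count was 9, and without nitrate replicate 1 or 2 it was 103 or 135, without chloride replicate 1, 2 or 3 it was 147, 453 or 84.

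At 11 h in T250 the nitrate transport genes stood out beside the reduction genes. NIP1-1 (GRMZM2G041980) was at least 10.8-fold higher with nitrate, NIR (GRMZM2G079381) 17.3-fold, gln3 (GRMZM2G046601) 16.4-fold, nrt2.2 (GRMZM2G010251) 11.4-fold (3.51 ± 0.37) and NAR (GRMZM5G878558) 11.1-fold (3.48 ± 0.25). GRMZM2G010280 was 5.28-fold higher, and NAR2.1 (GRMZM2G179294) rose by 1.82 ± 0.28 and the ferredoxin-dependent glutamate synthase fgs1 (GRMZM2G036609) by 1.29 ± 0.16, while Hb2 (GRMZM2G168898) was at least 5.34-fold higher. Lists that passed with both correlations, given here with the adjusted p of the estimated correlation, were nitrate transport (4 of 15 rose, adjusted p = 0.022), reduction (5 of 6 rose, 0.00050), ammonium assimilation (7 rose and 3 fell, 0.00088), reductant supply (3 of 9 rose, 0.0054), cytokinin (6 of 13 rose, 0.0093) and aquaporins (4 of 8 rose, 0.023). CCD8 (GRMZM2G446858) and pht2 (GRMZM2G154090) were 5.31-fold and 2.65-fold lower, the HD-ZIP gene gt1 (GRMZM2G005624) at least 2.26-fold and lkrsdh1 of lysine breakdown (GRMZM2G181362) at least 1.93-fold. In total 936 genes rose and 1323 fell. The count of 2259 became 1352 without nitrate replicate 1, which leaves the arrays of 1 slide, and 1374 without nitrate replicate 2 or 1427 without chloride replicate 3.

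At 12 h in T250 NIP1-1 (GRMZM2G041980) was at least 9.98-fold higher, NIR (GRMZM2G079381) 14.6-fold (3.87 ± 0.27), sum1 (GRMZM2G105604) at least 9.79-fold, gln3 (GRMZM2G046601) 10.4-fold and nrt2.2 (GRMZM2G010251) 9.33-fold, and Hb2 (GRMZM2G168898) rose by 2.44 ± 0.21. CCD8 (GRMZM2G446858) was 4.29-fold lower, and NAC12 (GRMZM2G018436, -1.87 ± 0.23) and pht2 (GRMZM2G154090, -1.15 ± 0.26) fell too. All 6 reduction genes rose (median 2.32, adjusted p = 6.9e-15, and 0.0057 with an estimated correlation). In total 1699 genes rose and 2306 fell. The count of 4005 became 2659 without nitrate replicate 2, 1901 without nitrate replicate 3, 1542 without chloride replicate 2 and 1294 in a fit of the 6 arrays alone. Chloride replicate 2 stood apart: its scan setting was 590 against 570 for the other T250 arrays, its lowest correlation with an array of its group was 0.961, and its array weight was 0.237. At 11 h and 12 h 548 genes rose in both and 955 fell in both, against 40.5 and 77.8 that independent lists would share, and 0 went opposite ways.

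Between 5 h and 12 h the response of T250 grew at several of these genes, as the test of the change itself showed. The difference between nitrate and chloride rose by 2.98 ± 0.52 at nrt2.2 (GRMZM2G010251, adjusted p = 0.0033), by 2.13 ± 0.30 at Hb2 (GRMZM2G168898), by 1.94 ± 0.31 at GLB1 (GRMZM2G067402), by 1.52 ± 0.22 at GRMZM2G078472 and by 1.27 ± 0.24 at FDX6 (GRMZM2G106190). In a fit of the 12 arrays alone GLB1 and GRMZM2G078472 did not pass (adjusted p = 0.057 for both), and with the brightest transcript model GRMZM2G078472 had 0.93 and did not pass. Of the 6 reduction genes 3 rose in the change, 5 when adjusted over the list alone (median 1.54, adjusted p = 6.5e-09, and 0.035 with an estimated correlation), and of 14 ammonium assimilation genes 2, or 4 when adjusted over the list alone (adjusted p = 0.00073, and 0.035 with an estimated correlation). In total 101 genes rose and 114 fell in the change. This count of 215 rests on single arrays: it was 108, 125 or 131 without 5 h nitrate replicate 1, 2 or 3, 112 without 5 h chloride replicate 3, 73 without 12 h nitrate replicate 3, and 343, 104 or 365 without 12 h chloride replicate 1, 2 or 3.

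In Lo5, as the mean over 1, 2 and 4 h, the largest fitted rises with nitrate among named genes were at heat shock genes. The small heat shock protein gene hsp18c (GRMZM2G034157) was at least 7.64-fold higher (adjusted p = 1.1e-15), hsp18f (GRMZM2G083810) 4.44-fold higher (2.15 ± 0.13) and HSP18 (GRMZM2G404249) at least 5.25-fold higher. All 6 members of the heat shock list rose, also when adjusted over the list alone (median 0.99, adjusted p = 2.2e-19, and 5.1e-06 with an estimated correlation), among them hsp82 (GRMZM5G833699, 1.39 ± 0.17), hsp1 (GRMZM5G802801, 1.01 ± 0.09) and Hsp70 (GRMZM2G310431, 0.59 ± 0.07). For hsp1 and Hsp70 6 of 9 nitrate arrays lay above the mean of their chloride group.

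Some nitrogen genes moved in Lo5 too. NIR (GRMZM2G079381) was 1.61-fold higher (0.69 ± 0.15, adjusted p = 0.0066) in 9 of 9 nitrate arrays and gln1 (GRMZM2G098290) 1.69-fold higher (0.76 ± 0.12), whereas Gln1-4 (GRMZM2G036464) fell by 0.41 ± 0.09. Of the 6 reduction genes 3 rose, also when adjusted over the list alone (median 0.40, adjusted p = 0.0022, and adjusted p = 0.36 with an estimated correlation). Of 5 nitrate signalling regulators 3 rose, 4 when adjusted over the list alone (median 0.46, adjusted p = 0.0022, and 0.011 with an estimated correlation); in T250 the median of this list was 0.08, and the difference of T250 from Lo5, -0.35, did not pass (adjusted p = 0.077). None of the 15 nitrate transport genes passed the test over all genes, and 1 fell when adjusted over the list alone (adjusted p = 0.51 for the list). Both strigolactone synthesis genes fell, also when adjusted over the list alone, CCD7 (GRMZM2G158657, -0.71 ± 0.16) among them. Of 9 phenylpropanoid genes 2 fell, 4 when adjusted over the list alone, PAL1 (GRMZM2G074604, -0.41 ± 0.08) among them (adjusted p = 0.00071 for the list, and adjusted p = 0.10 with an estimated correlation). The clock genes gigz1b (GRMZM5G844173) and GRMZM2G095727 rose by 0.72 ± 0.09 and 0.93 ± 0.09, sus2 (GRMZM2G318780) was at least 1.80-fold higher, and the glutathione transferase gst30 (GRMZM2G044383) fell by 0.79 ± 0.17. The brightest transcript model alone gave gln1 a difference of 0.35 and PAL1 one of -0.17, neither past the test.

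In total 1045 genes rose and 992 fell in the mean of Lo5 (limma). Fewer genes passed with each line fitted separately or with only the arrays compared, and more with array weights, as given below. Nitrate, slide and place on the slide cannot be told apart at 2 h. The mean of 1 h and 4 h, each within a slide, called 6890 genes, of which 1107 were among the 2037 of the mean of 3 times, and without 1 h nitrate replicate 2 the count was 1347. The random-probe level shifted the same way at 1 h and at 4 h, and the mean of these times does not separate that shift from nitrate.

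At 1 h in Lo5 the heat shock list had its largest median among the times sampled. With nitrate hsp18c (GRMZM2G034157) stood at 12.32 ± 0.19, at least 12.3-fold above chloride (adjusted p = 1.8e-13), where 1 of 3 arrays lay above background. The heat shock factor Hsf26 (GRMZM2G003489) was at least 16.8-fold higher and HSP18 (GRMZM2G404249) at least 13.4-fold. All 6 heat shock list members rose, also when adjusted over the list alone (median 3.11, adjusted p = 1.1e-27, and 1.7e-07 with an estimated correlation): hsp1 (GRMZM5G802801) 9.46-fold, hsp82 (GRMZM5G833699) 8.90-fold and Hsp70 (GRMZM2G310431) 3.12-fold, and outside the list hsp22 (GRMZM2G007729) 10.6-fold. Of 9 clock genes 2 rose, 3 and 2 in opposite directions when adjusted over the list alone (adjusted p = 0.0032, and adjusted p = 0.11 with an estimated correlation): GRMZM2G095727 by 2.24 ± 0.15 and gigz1b (GRMZM5G844173) by 1.62 ± 0.15. The glutamine synthetase gene gln1 (GRMZM2G098290) rose by 1.27 ± 0.20, and the aquaporin TIP4-1 (GRMZM2G103945) fell by 1.00 ± 0.15; with the brightest transcript model alone these were 0.52 and -0.56 and did not pass, nor did either in a fit of the 6 arrays alone (adjusted p = 0.078 and 0.063).

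In total 1053 genes rose and 388 fell at 1 h in Lo5. The count of 1441 was 633 with the random-probe level of each array as a covariate and 188 in a fit of the 6 arrays alone. With array weights it was several times higher, as given below. It was 826 or 894 without nitrate replicate 2 or 3, and 689 or 2703 without chloride replicate 1 or 3.

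**Figure D3:**
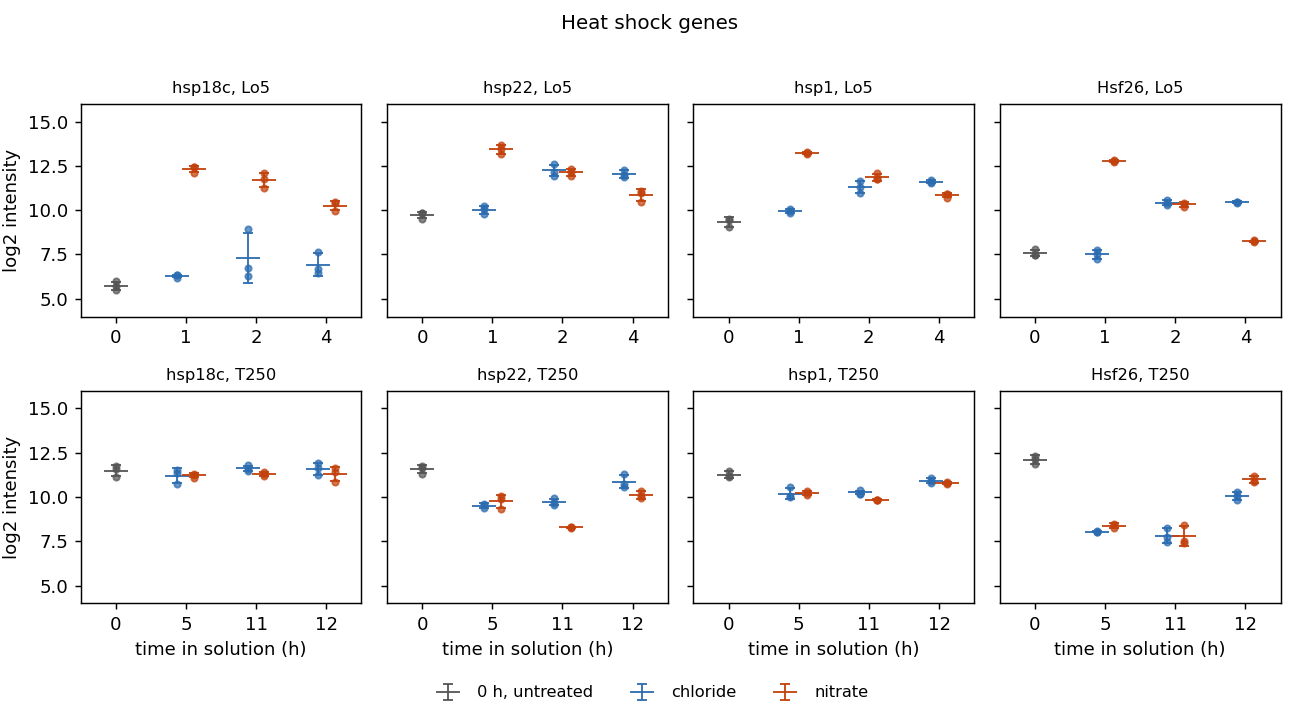
Log2 intensity (vertical axis) against hours in solution (horizontal axis) for hsp18c, hsp22, hsp1 and Hsf26 in Lo5 (upper row) and T250 (lower row); points are single arrays, bars the mean ± SD of 3 arrays. In Lo5 at 1 h Hsf26 lies at 12.77 with nitrate and 7.51 with chloride, and at 4 h at 8.24 and 10.46.

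At 2 h in Lo5 hsp18c (GRMZM2G034157) was still at least 10.9-fold higher, HSP18 (GRMZM2G404249) 11.4-fold (3.51 ± 0.26) and hsp18f (GRMZM2G083810) 4.55-fold (2.19 ± 0.23). All 6 heat shock list members rose, also when adjusted over the list alone (median 1.02, adjusted p = 0.00020, and adjusted p = 0.070 with an estimated correlation). The transcription factor gene DOF10 (GRMZM2G435475) was at least 2.27-fold higher and es4 (GRMZM2G009359) at least 2.17-fold, and the cytokinin oxidase genes CKX6 (GRMZM2G404443) and CKX12 (GRMZM2G008792) rose by 1.23 ± 0.25 and 1.12 ± 0.16. The flavonoid gene f3h (GRMZM2G062396), flavanone 3-hydroxylase, was at least 3.49-fold lower and the auxin transporter PIN8 (GRMZM5G839411) at least 1.66-fold, and bHLH84 (GRMZM2G159456, -1.65 ± 0.24) fell, as did the clock gene GRMZM2G148453 (-1.65 ± 0.18).

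In total 6647 genes rose and 5609 fell at 2 h in Lo5. Since the nitrate and chloride arrays lay on different slides and at different places, treatment, slide and place cannot be told apart in these values. With the random-probe level as a covariate the count of 12256 was 2933.

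At 4 h in Lo5 some heat shock genes were lower with nitrate and hsp18c was still higher. Hsf26 (GRMZM2G003489, -2.22 ± 0.19), hsp1 (GRMZM5G802801, -0.76 ± 0.15) and Hsp70 (GRMZM2G310431, -0.56 ± 0.13) fell, while hsp18c (GRMZM2G034157) was at least 3.33-fold higher (fitted log2 difference 3.33 ± 0.38). Of the 6 heat shock list members 3 fell, also when adjusted over the list alone (median -0.50, adjusted p = 0.026, and adjusted p = 0.42 with an estimated correlation). NLP8 (GRMZM2G176655), of the family of nitrate-responsive regulators, rose by 1.36 ± 0.26 and ocl1 (GRMZM2G026643) by 1.42 ± 0.29, atGRF5 (GRMZM2G105335) was at least 2.46-fold higher, and the alternative oxidase gene Aox (GRMZM2G125669) fell by 1.35 ± 0.26. Of 9 cell cycle genes 3 rose, 4 when adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.42 with an estimated correlation). Of these genes hsp18c, Hsf26 and hsp1 passed the test with the random-probe level as a covariate, and NLP8, ocl1, atGRF5, Aox and Hsp70 did not. In a fit of the 6 arrays alone ocl1 did not pass (adjusted p = 0.061).

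In total 2265 genes rose and 2054 fell at 4 h in Lo5, and with the random-probe level as a covariate the count of 4319 was 127. Without nitrate replicate 2 or 3 it was 727 or 2826, and without chloride replicate 1, 2 or 3 it was 2472, 1484 or 2570. In the 4 h chloride group NIR (GRMZM2G079381) spread widely, 11.35 ± 0.81 against 11.93 ± 0.13 with nitrate.

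From 1 h to 4 h the heat shock difference in Lo5 fell throughout the list, as the test of the change showed. The difference at Hsf26 (GRMZM2G003489) fell at least 77.9-fold (adjusted p = 2.3e-19). It also fell at ERTC (GRMZM2G051135, at least 17.3-fold), hsp22 (GRMZM2G007729, -4.61 ± 0.29), hsp101 (GRMZM2G360681, 18.4-fold), hsp1 (GRMZM5G802801, adjusted p = 5.1e-15) and Hsp70 (GRMZM2G310431, 4.59-fold). All 6 list members fell in the change, also when adjusted over the list alone (median -3.59, and -3.45 with a member at its bound; adjusted p = 4.5e-29, and 1e-07 with an estimated correlation). The clock gene GRMZM2G095727 fell by 2.21 ± 0.21, and GRMZM2G020081, also of the clock list, rose by 1.00 ± 0.17. In total 266 genes rose and 580 fell in the change. The count of 846 was 543 without 4 h nitrate replicate 2, 524 with each line fitted separately and 354 in a fit of the 12 arrays alone. It was 1247 without 1 h chloride replicate 1 and higher still with array weights, as given below.

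At 1 h and 4 h in Lo5 61 genes rose in both and 52 fell in both, against 60.8 and 20.3 for independent lists, while 108 went opposite ways (77.6). Across genes, which are not independent replicates, the differences at these times had r = 0.344. In T250 r was 0.323 for 5 h and 11 h, 0.293 for 5 h and 12 h and 0.721 for 11 h and 12 h. Between 2 h and the other times in Lo5 338 genes went opposite ways with 1 h, against 216 for independent lists (r = -0.343), and 1674 with 4 h, against 672 (r = -0.371). The random-probe level moved in the same alternation (-0.26, 0.39 and -0.35), and at 2 h the treatment cannot be told apart from the slide or the place on it.

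The test of the difference between the lines set the mean nitrate effect in T250 against that in Lo5; the lines were sampled at different times, so line and time cannot be told apart in it. The rise was larger in T250 at least 6.47-fold at NIP1-1 (GRMZM2G041980, adjusted p = 3.1e-11), at least 4.26-fold at sum1 (GRMZM2G105604) and at least 2.76-fold at FDX6 (GRMZM2G106190). It was larger by 2.76 ± 0.22 at gln3 (GRMZM2G046601), 2.71 ± 0.22 at NIR (GRMZM2G079381), 2.38 ± 0.18 at GLB1 (GRMZM2G067402), 2.02 ± 0.30 at nrt2.2 (GRMZM2G010251), 1.99 ± 0.21 at NAR (GRMZM5G878558) and 0.59 ± 0.13 at PIP2-4 (GRMZM2G154628). All 6 reduction genes differed this way, also when adjusted over the list alone (median 1.68, adjusted p = 8.9e-13, and 0.0066 with an estimated correlation). In the ammonium assimilation list 6 were higher and 2 lower (8 and 2 when adjusted over the list alone; adjusted p = 0.00010, and 0.0087 with an estimated correlation), and in reductant supply 3 of 9 were higher, also when adjusted over the list alone (adjusted p = 0.00066, and 0.016 with an estimated correlation). The heat shock difference ran the other way: 5 of 6 list members were lower, also when adjusted over the list alone (median -1.11, adjusted p = 2.2e-10, and 0.00087 with an estimated correlation), hsp1 (GRMZM5G802801) by -1.18 ± 0.12 and, outside the list, hsp18c (GRMZM2G034157) at least 8.79-fold. CCD8 (GRMZM2G446858) fell further in T250, at least 2.41-fold.

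In total the nitrate effect was higher in T250 at 1484 genes and lower at 2019. With the random-probe level as a covariate the count of 3503 was 2133, and with the Lo5 effect as the mean of the times within a slide it was 9554, of which 2816 were shared. Of the genes that passed in the means of both lines 143 rose in both, against 71.7 for independent lists, 307 fell in both (99.1), and 112 went opposite ways (172).

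The chloride controls against 0 h show what moved without added nitrate. In Lo5 some heat shock and clock genes rose. The gene hsp101 (GRMZM2G360681) was 3.35-fold higher (1.74 ± 0.26), hsp22 (GRMZM2G007729) 3.26-fold and hsp1 (GRMZM5G802801) 3.06-fold. Of the 6 heat shock list members 4 rose and 1 fell, also when adjusted over the list alone (median 0.67, and 0.50 with members at their bound; adjusted p = 9.3e-05, and adjusted p = 0.052 with an estimated correlation). Of 9 clock genes 3 rose and 2 fell, 5 and 2 when adjusted over the list alone (adjusted p = 0.0065, and adjusted p = 0.16 with an estimated correlation): GRMZM2G095727 rose by 1.73 ± 0.12 and gigz1b (GRMZM5G844173) by 1.44 ± 0.12. Pyruvate decarboxylase PDC (GRMZM2G038821) rose by 1.41 ± 0.27, 1 of the 6 low oxygen genes that did, 2 when adjusted over the list alone (adjusted p = 0.049, and adjusted p = 0.28 with an estimated correlation). NF-YA4 (GRMZM2G008250, -0.90 ± 0.12) and TIP4-1 (GRMZM2G103945, -0.63 ± 0.12) fell, and Baf1R-1 (GRMZM2G029096) was at least 1.89-fold lower.

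In total 1747 genes rose and 1403 fell from 0 h to the chloride controls of Lo5, and 1 h and 2 h chloride, on the slide of the 0 h group, gave 3030 genes. The single times differed: 1 gene passed between 1 h chloride and 0 h, 11182 between 2 h chloride and 0 h, and 5122 between 4 h chloride, on another slide, and 0 h. On their slide 0 h lay at places 1 to 3, 1 h chloride at 4 to 6 and 2 h chloride at 10 to 12. The random-probe medians were 6.16 to 6.48, 6.12 to 6.43 and 5.85 to 5.90 in these groups. Time and place on the slide therefore cannot be told apart in these counts. The count of 3150 was 1325 or 551 without 0 h replicate 2 or 3, 4761 without 1 h chloride replicate 1, and 882 with the random-probe level as a covariate.

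In T250 some of the nitrate genes dropped from 0 h to the chloride controls. Falls were seen at nrt2.2 (GRMZM2G010251, -1.91 ± 0.30), NAR (GRMZM5G878558, -1.62 ± 0.21), gln3 (GRMZM2G046601, -1.32 ± 0.22), NIR (GRMZM2G079381, -1.27 ± 0.22) and CKX6 (GRMZM2G404443, -1.22 ± 0.20). Of the 6 reduction genes 3 fell, 4 when adjusted over the list alone (median -0.92, adjusted p = 5.3e-07, and adjusted p = 0.058 with an estimated correlation), and of 15 nitrate transport genes 4, or 5 when adjusted over the list alone (adjusted p = 0.0020, and adjusted p = 0.16 with an estimated correlation). Of 8 aquaporins 5 fell, also when adjusted over the list alone (adjusted p = 5.9e-06, and adjusted p = 0.051 with an estimated correlation), pip2b (GRMZM2G092125, -0.63 ± 0.11) among them. Of the 6 heat shock list members 3 fell, 4 when adjusted over the list alone (median -0.51, and -0.30 with members at their bound; adjusted p = 0.00018, and adjusted p = 0.052 with an estimated correlation). The genes hsp101 (GRMZM2G360681, -1.66 ± 0.26) and hsp22 (GRMZM2G007729, -1.53 ± 0.17), which rose in Lo5, fell, and the difference from Lo5 was not tested. Hsf26 (GRMZM2G003489) was at least 7.66-fold lower and YS3 (GRMZM2G063306) at least 3.22-fold higher. In total 855 genes rose and 712 fell. The count of 1567 was 529 or 948 without 0 h replicate 2 or 3, 959 with the slide as a block and 1033 in a fit of the 12 arrays alone. With array weights it was several times higher, as given below.

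Between the lines at 0 h, T250 against Lo5, some heat shock and clock genes were higher in T250. The small heat shock gene hsp18c (GRMZM2G034157) was at least 6.08-fold higher and Hsf26 (GRMZM2G003489) at least 9.41-fold higher. Of the 6 heat shock list members 3 were higher, also when adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.23 with an estimated correlation). Of 9 clock genes 5 were higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.040, and adjusted p = 0.32 with an estimated correlation): GRMZM2G474769 by 1.96 ± 0.18, GRMZM2G095727 by 1.92 ± 0.15 and gigz1b (GRMZM5G844173) by 1.80 ± 0.15. The nitrate transport genes nrt2.2 (GRMZM2G010251) and NAR2.1 (GRMZM2G179294) were 3.60-fold and 3.39-fold higher in T250, nicotianamine synthase nas2 (GRMZM2G030036) at least 9.90-fold, phyS11 (GRMZM2G140101) 9.12-fold and Gln1-4 (GRMZM2G036464) 2.26-fold. The receptor kinase gene hk3 (GRMZM2G158252) lay below background in every Lo5 array at 0 h and was at least 1.18-fold higher in T250. GLP2 (GRMZM2G122018) was at least 4.77-fold lower in T250, ARGOS7 (GRMZM2G113583) at least 1.69-fold, and HIT2 (GRMZM2G126765, -2.02 ± 0.18) was lower too.

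In total 3853 genes were higher in T250 at 0 h and 3264 lower. With the normalization as deposited, within each line, 3608 were higher and 4594 lower, so the balance depends on the normalization. The count of 7117 was 3934 with only the arrays compared and 10968 with array weights. By the reading of the scan names used here the lines never shared a slide, so line and slide cannot be told apart. Sequence differences between the lines can also change how a probe binds. Of the probes of the higher and lower genes 89.5% and 91.9% had the sign of their gene, against 95.8% and 93.4% for the mean nitrate effect in T250. The gene values come from these same probes, so high shares are built in and cannot show whether binding differs between the lines.

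The lists of genes of green tissue and of kernels were tested for differences between groups, which does not show whether such tissue was present. Neither passed with both correlations in any of the 14 comparisons. Of 6 photosynthesis genes 1 rose in the mean of Lo5 (median -0.04, mean 0.20, list adjusted p = 0.72) and 0 in the mean of T250 (median 0.16, adjusted p = 0.15); the median and the test differ in sign in Lo5. Of 13 seed storage genes 0 changed in Lo5, 3 fell when adjusted over the list alone (median -0.12, adjusted p = 0.031, and adjusted p = 0.36 with an estimated correlation), and in T250 1 rose (adjusted p = 0.27). With the preset correlation this list also passed at 4 h in Lo5 and between the nitrate effects of the lines (adjusted p = 0.016 in each). In T250 the lists of low oxygen (adjusted p = 0.14), cell wall (0.11), peroxidase (0.27), auxin (0.26) and organic acid genes (0.95) did not pass the test.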

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

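The tests of the difference between slides, of the background level, of responses that last to 4 h, and both tests on the 4 h chloride array were chosen only after the result was seen. The correlation with T250, the course of the chloride controls and the splits of the arrays were set before.

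The nitrate effect differed between the lines at 3503 genes by the test of the difference itself. Of 100 splits of the arrays 1, the real one, gave as many, with 1088 genes in the highest of the others, which argues against chance. The splits still carry the differences within the times, so they do not exclude it. The lists that differed were nitrate and nitrite reduction (median 1.68), ammonium assimilation (0.52) and reductant supply (0.33), higher in T250, and heat shock and chaperones (-1.11), lower in T250. The lines were sampled at different times, so line and time cannot be told apart.

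The effect changed between 1 h and 4 h in Lo5 at 846 genes, and the heat shock list moved by a median of -3.59, or -3.45 with a member at its bound. Of 100 splits 3 gave as many genes, the real one included, a share under 0.05. The splits still carry the differences within the times, so this share does not exclude chance for the change. The highest of the others called 6890 genes and exchanged the whole 4 h groups, which makes it the sum of the 1 h and 4 h differences. The background shifts of these times add up in it as well, to a random-probe difference of 0.61 against -0.09 in the real split, so this structure of the samples holds the treatment and the background together. The effect changed between 5 h and 12 h in T250 at 215 genes, with medians of 1.54 in nitrate and nitrite reduction and 0.28 in ammonium assimilation. Here 10 of 100 splits gave as many, so chance cannot be excluded for the count. The highest, 3684 genes, exchanged the whole 5 h groups and so counts the sum of the 5 h and 12 h differences, and splits that carry this sum are no measure of chance for the change. Without 12 h nitrate replicate 3 the T250 count was 73 and without 12 h chloride replicate 3 it was 365; further values stand with the result above.

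More genes passed between nitrate and chloride at 2 h in Lo5 (12256) than at 1 h (1441) or 4 h (4319). The 2 h groups lay on different slides and at different places, nitrate at 4 to 6 and chloride at 10 to 12. Of the random-sequence probes, which match no transcript, 25.7% passed between them, against 0 and 0.481% at the other times. The slide or the place may therefore account for part of the count. The 2 h difference also followed the mean nitrate effect in T250 across genes (r = 0.282, against -0.10 at 1 h and -0.03 at 4 h). Genes are not independent replicates. A broader nitrate response at 2 h would give this order. A shared background could give it too, since the random-probe level moved by 0.085 in the mean of T250, in the direction it took at 2 h and not at 1 h or 4 h. The places ran alike: nitrate lay at lower places than chloride at 2 h in Lo5 and at 5 h and 12 h in T250. It lay at higher places at 1 h and 4 h in Lo5, and on both sides of chloride at 11 h in T250. With the random-probe level as a covariate 2933 genes passed and r was 0.218, against -0.02 at 1 h and 0.11 at 4 h with the same covariate, a smaller gap. These explanations stay open, and at 2 h treatment, slide and place on the slide are confounded.

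Heat shock genes were higher with nitrate at 1 h in Lo5, by a median of 3.11. The background level of the arrays is argued against, since with it as a covariate 103% of the median was kept. For the list a response that lasts to 4 h is argued against too, since the median was -0.50 at 4 h (0 rose and 3 fell; adjusted p = 0.42 with an estimated correlation) and all 6 members fell in the tested change. It stays open for hsp18c (GRMZM2G034157), which was still at least 3.33-fold higher at 4 h (fitted log2 difference 3.33 ± 0.38, and 1.73 with chloride at the background bound; adjusted p = 8.7e-06, in 3 of 3 nitrate arrays). A brief response, which T250 sampled from 5 h on could not show, stays open for the list. The 1 h chloride roots might instead have been earlier along a course that the chloride controls also took: of the 11182 genes that differed between 2 h chloride and 0 h, 90.8% were further along in the 1 h nitrate group, but 67.4% with the random-probe level as a covariate. Such a course would give the 1 gene that passed between 1 h chloride and 0 h and the 4311 between 1 h nitrate and 0 h. It would also give the levels of the clock gene gigz1b (GRMZM5G844173). These were 9.47 at 0 h and 9.59 at 1 h with chloride, but 11.22 at 1 h with nitrate and 11.23 at 2 h with chloride. These groups lay on 1 slide in that order, at places 1 to 3, 4 to 6, 7 to 9 and 10 to 12. Neither these values nor the shares further along therefore tell the course from the place. Against the course, the list median stood 3.33 above 0 h with nitrate at 1 h. The chloride controls reached 0.14, 0.73 and 1.25 at 1, 2 and 4 h, so no sampled point of that course came near. A peak between the sampled times would not be seen, and the background of the arrays runs in the direction of that course, so these explanations cannot be told apart.

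In the 4 h chloride group of Lo5, replicate 3 had nitrate-responsive genes at a mean level of 10.16, near the 10.29 to 10.40 of the nitrate arrays and above the 9.87 and 9.89 of the other chloride arrays. A swap with a 4 h nitrate array is argued against, since the lowest nitrate array lay 0.39 above the higher of the other chloride arrays and none was out of place. In this array NIR (GRMZM2G079381, 12.29), nrt2.2 (GRMZM2G010251, 14.03) and gln3 (GRMZM2G046601, 12.34) lay above every 4 h nitrate array, whose highest values were 12.07, 13.67 and 12.27. In contrast CCD8 (GRMZM2G446858, 10.03) and Hsf26 (GRMZM2G003489, 10.48) lay within the range of the other chloride arrays, and hsp18c (GRMZM2G034157) lay at 6.44, under the 6.70 and 7.64 of the other chloride arrays and far from the 9.95 to 10.44 with nitrate. Roots that met nitrate under a chloride label may explain the level, but the mean of 10.16 lies between the groups and single genes go both ways, which leaves this open, and no biological explanation was tested.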

How the results depend on the processing

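The normalization as deposited, the normexp offset of 0, the random-probe covariate and the times within a slide were chosen after seeing the data, and the array weights were taken gene by gene because the default method did not converge. No count changed by over 1.5 times with either normexp offset, without the dim genes, with the brightest transcript model, with the replicate number as a block or with the normalization as deposited, nor for the lines at 0 h with the median over probes, run only there. As deposited the 8202 genes between the lines at 0 h split into 3608 higher and 4594 lower, against 3853 and 3264. Median centring could not be run, since the deposited values were already quantile normalized. No named gene changed direction under any alternative. Of 166 named values 6 lost their call with the brightest transcript model, 10 with only the compared arrays and 5 with the covariate; none did on leaving out an array, because genes that did were not printed.

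With each line fitted separately the mean of Lo5 had 1121 genes, 1 h in Lo5 924 and the change in Lo5 524. With only the arrays compared there were 1010 genes in the mean of Lo5, 188 at 1 h, 354 in its change, 9 at 5 h in T250, 1294 at 12 h and 59 in its change, 1383 and 1033 from 0 h to chloride in Lo5 and T250, and 3934 between the lines; fewer arrays estimate the spread there. With array weights there were 4799 in the mean of Lo5, 5046 at 1 h, 8351 at 4 h and 3700 in its change, 680 at 5 h and 3618 at 11 h in T250, 5956 and 6063 from 0 h to chloride in Lo5 and T250, and 10968 between the lines; the cause was not tested. With the slide as a block T250 had 959 genes from 0 h to chloride. With the random-probe level as a covariate there were 633, 2933 and 127 genes at 1, 2 and 4 h in Lo5, 2133 between the nitrate effects of the lines and 882 from 0 h to chloride in Lo5. With the times within a slide there were 6890 in the mean of Lo5 and 9554 between the nitrate effects; the random-probe level shifts alike at 1 h and 4 h (-0.26 and -0.35), and the cause was not tested.

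On leaving out each array in turn the counts ran from 1347 to 2358 in the mean of Lo5, 689 to 2703 at 1 h, 8634 to 11079 at 2 h, 727 to 3298 at 4 h and 543 to 1247 in its change. In T250 they ran from 4862 to 7437 in the mean, 84 to 453 at 5 h, 1352 to 2242 at 11 h, 1542 to 5522 at 12 h and 73 to 365 in its change. They ran from 2751 to 4129 between the nitrate effects, 551 to 4761 and 529 to 1850 from 0 h to chloride in Lo5 and T250, and 5104 to 6464 between the lines; the arrays that moved a count by over 1.5 times are named beside it, and no array did so in the mean of T250, at 2 h in Lo5, between the nitrate effects or between the lines. A lone pair left in a group was assumed to vary like the other groups. Genes with a level under the random-probe percentile allow only bounds, and as few as 47.2% of the gene models had a level above it on an array.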

Other observations

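The overlap with T250 and the families formed from gene names were chosen only after the data were seen; the splits of the arrays were set before.

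Most genes that responded by at least 1 in T250 had the same sign in the mean of Lo5, but not those that fell at 1 h. Of 181 genes that rose by at least 1 on the log2 scale in the mean of T250, 153 (84.5%) were higher with nitrate in the mean of Lo5, with a median of 0.25, and 30 passed the test there while 1 passed in the opposite direction. Of 306 that fell, 225 (73.5%) were lower in Lo5, with a median of -0.17, and 22 passed while 4 passed in the opposite direction. Over all genes 49.4% were higher and 50.6% lower in the mean of Lo5. At single times in Lo5 71.3%, 66.9% and 75.1% of the genes that rose in T250 were higher at 1, 2 and 4 h, against 44.2%, 52.2% and 46.4% of all genes. Of those that fell 50.3%, 67.6% and 65.0% were lower, against 55.8%, 47.8% and 53.6% of all genes, with a median of -0.01 at 1 h. With the random-probe level as a covariate the shares at 1, 2 and 4 h were 59.7%, 72.9% and 61.3% for the genes that rose. For those that fell they were 48.4%, 66.3% and 62.4%. At 2 h the treatment cannot be told apart from the slide or the place on it.

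With chloride some single genes stood at different levels at different times; these genes were chosen after their values were seen. In T250 Hsf26 (GRMZM2G003489) stood at 12.12 ± 0.23 at 0 h, 8.04 ± 0.02 at 5 h, 7.83 ± 0.40 at 11 h and 10.06 ± 0.24 at 12 h with chloride (log2 ± SD, n = 3). The clock gene gigz1b (GRMZM5G844173) went from 11.27 ± 0.20 to 12.84 ± 0.12, 10.07 ± 0.36 and 11.22 ± 0.10 in the same groups, whereas the heat shock gene hsp18c (GRMZM2G034157) stayed between 11.21 and 11.62.

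Of the 24 families formed from names 2 passed with both correlations in some comparison. The 21 genes named HSF or HSP passed in the mean of Lo5 (11 rose, median 0.46), at 1 h in Lo5 (13 rose, 1.23), in the change in Lo5 (13 fell, -1.40) and between the nitrate effects of the lines (11 lower in T250, -0.57). They also passed from 0 h to chloride in Lo5 (11 rose and 1 fell, 0.48) and in T250 (1 rose and 7 fell, median -0.02, mean -0.47), and between the lines at 0 h (9 higher and 2 lower in T250, 0.54). The 24 named aquaporins passed from 0 h to chloride in T250 (1 rose and 10 fell, median -0.33, 0.032 with an estimated correlation).

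The splits of the arrays gave these results for the other comparisons. In the mean of T250 1 of 100 splits, the real one, gave as many genes (6609, and 1682 in the highest of the others), which argues against chance. The splits still carry the differences within the times, so they do not exclude it. At each time nitrate and chloride shared no place, so the real split is also a split by place. In the mean of Lo5 5 of 100 gave as many as 2037, so chance cannot be excluded, and the highest, 5511 genes, exchanged the whole 2 h groups, which lay on different slides, 2 of 3 arrays of each group at 1 h and 1 of 3 at 4 h; such splits still carry the differences within the times and are no pure measure of chance. From 0 h to chloride 7 of 100 splits gave as many in Lo5 (3150, highest 7431) and 8 of 100 in T250 (1567, highest 4888), so chance cannot be excluded for either count; splits that call several times the real count point to a structure of the samples. The times also differ in slide, in place on it and in background, with random-probe differences of 0.24 and 0.21 in the highest splits, and which of these gives the structure was not tested. For groups of 3 against 3 the 10 splits are too few for a share under 0.05: the real split gave 1441, 12256 and 4319 genes at 1, 2 and 4 h in Lo5 (highest other 1, 9 and 2), 238, 2259 and 4005 at 5, 11 and 12 h in T250 (1, 1 and 3), and 7117 between the lines at 0 h (11). In each of these 7 comparisons 1 of 10 splits, the real one, gave as many.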
